A study of Mus musculus with 17 samples.

How the data were processed

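Total RNA from the pancreatic lymph nodes (PLN) of individual female non-obese diabetic (NOD) mice was hybridised to 17 Agilent whole mouse genome arrays with a pool of age-matched NOD.B10 nodes on the same array. NOD mice develop autoimmune diabetes spontaneously, and NOD.B10 mice, by their name, carry the H2 (major histocompatibility) region of a B10 strain on the NOD background. The ages were 10 days (6 arrays), 4 weeks (6 arrays) and 12 weeks (5 arrays). Per the labels, RNA was extracted with Trizol and RNeasy and labelled by linear amplification, with NOD in Cy5 and the pool in Cy3 on every array. No array had the dyes swapped, so a dye effect specific to a gene cannot cancel. A single pool stood for the control at each age, so the mean ratio was tested against 0, which leaves out the control's own spread.

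Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1 at 10 days and 10.5.1.1 at 4 and 12 weeks, with probe positions on the mm9 genome build. Signals and local backgrounds in these files are intensity values in scanner units, per the file headers. The scanner software's own ratio of processed Cy5 over Cy3 is on a log10 scale, per the file headers. The table of the authors held 41267 probes with values on a log2 scale, as the log2 of the processed Cy5 over Cy3 ratio in the labelled direction. The scale was found by comparing each array with its scanner ratio, since the labels do not state it. The columns of that table were not centred. Their medians ranged from -0.09 to 0.277 log2.

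Each array held 45018 spots, of which 43379 were not controls, and these came to 41174 different probes. Median spot signals were corrected with limma 3.58.1 (R 4.3.3, jsonlite 2.0.0, and the data.table package in version 1.17.8) by normexp with an offset of 50, and the log2 ratios were normalised within each array by loess with a span of 30% of the spots. The mean spot signal was absent from part of the files, so the median signal was used throughout. No scaling between arrays was applied. A probe was kept when it was well above background in at least 1 channel on at least 0.5 of the arrays of some age, which left 27802 probes for 19344 genes, 14599 of them with a proper gene symbol. The brightest probe stood for each gene. Names were updated through the reference accession for 27050 probes, 14124 kept the name given in the file, and 2712 names changed. Missing values were left missing in 176 genes.

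A single limma model held one mean per age over all 17 arrays. The 3 mean ratios were tested against 0, and the 3 differences between ages were tested in the same model. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1.5-fold. All gene p-values below are these limma values, 2-sided. The named genes were chosen by a rule: for each NOD over NOD.B10 comparison, the 10 highest and 10 lowest called genes with a proper symbol and the same sign on every array; for each difference between ages, the 5 highest and 5 lowest whose arrays did not overlap; up to 4 called members of each gene list, or its 2 largest values where none was called; and Deaf1, Eif4g3, Ptbp2, Srsf10, Adora1, insulin and the classical H2 genes. Choices and gene lists were fixed before the data were examined, except where the text says otherwise.

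The 31 gene lists held 1078 genes, of which 980 were tested. They covered H2 class I, class II and other genes of the H2 region, pancreatic acinar and islet genes, peripheral tissue antigens, stromal, endothelial, fat and muscle markers, lymphoid and myeloid cell types, red cells, interferon responses, proliferation, splicing, a Deaf1 and translation list, type 1 diabetes regulators, the circadian clock, immediate early genes, ribosomal proteins and oxidative phosphorylation. Each list was compared with all other tested genes by limma's pre-ranked camera test with a preset correlation of 0.01, and again with a correlation estimated from the residuals and floored at 0. The pre-ranked form replaced the planned camera test because of the missing values. P-values were adjusted over the 31 lists of each comparison. Fisher's exact test (2-sided) compared called genes inside the H2 region of chromosome 17, and on each chromosome, with the genes elsewhere, among the 19117 genes with a position. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

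The share of probes well above background gave the depth of each array. In Cy5 it was 39.7% to 52.7% at 10 days, 11.1% to 24.2% at 4 weeks and 0.78% to 8.76% at 12 weeks. In Cy3 it was 63.1% to 67.9%, 51.1% to 64% and 10.4% to 13.4%. The number of arrays also limits the precision. The residual spread of a gene had a median SD of 0.14 log2, with 14 residual degrees of freedom and a prior of 4.12.

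The test was run on simulated data with known changes in 50 genes per size. At 1.5-fold it recovered 24 genes at 10 days, 18 at 4 weeks and 21 at 12 weeks. At 2-fold it recovered 50, 50 and 49, and at 4-fold all 50 at each age. False calls numbered 10, 8 and 2. With no change present, 14, 4 and 0 genes were called at the 3 ages. Close to 0 calls would be expected there, so some p-values at 10 days and 4 weeks were too small. The simulation gave each gene its own spread at each age, while the model shares a single spread over the ages. For H2-T3 at 10 days the standard error was 0.109 with an SD of 0.479 over 6 arrays. Adjusted p-values may thus be too small for genes that vary more at an age than over all ages. Lists were simulated for the comparison at 10 days only. There no list of the 31 was called without a simulated change (0 lists), and a shifted list was called with an adjusted p of 4.28e-84 and 0 others. The genes were simulated independently of each other, so this run cannot show how the list test behaves when members are correlated.

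Alternatives covered the offset (16), no background correction, the scanner ratio, the table of the authors, median centring, Aquantile and scale normalisation between arrays, other probe filters, the mean of a gene's probes, the p-value alone or a 2-fold limit, other moderation, array weights, each age alone, slide, scan and replicate number as blocks, and each array left out in turn. After the data were examined, loess spans of 5%, 2% and 1% were tried because the brightest probes kept a positive ratio under the 30% span, and the 2% span was taken for the values printed beside the others. Restricting the test to genes measured in both channels, leaving out both arrays of slide 3, leaving out 10-day arrays 1 and 3, and using scan 3 alone were also added then. The decision to lead with results that passed under the 30% span, the 2% span and the scanner ratio was made after the data were examined.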

Results

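Expression was measured in the pancreatic lymph nodes of 17 female NOD mice, 6 at 10 days, 6 at 4 weeks and 5 at 12 weeks of age, each as a log2 ratio over a pool of age-matched NOD.B10 nodes. These nodes drain the pancreas, where the autoimmune attack on the islets takes place. Signal was lower at the later ages. Genes above background in the NOD channel on most arrays numbered 14561 at 10 days, 5718 at 4 weeks and 349 at 12 weeks. The control channel gave 18655, 17687 and 4239 genes. Values are mean log2 ratios of NOD over NOD.B10 with SD, positions are on mm9, and gene p-values are adjusted limma values. The comparisons at each age ask which genes differ between NOD and NOD.B10 nodes. The differences between ages ask whether that contrast changes as the mice grow older.

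Genes of the Reg family, which encode secreted lectins made in the exocrine pancreas and gut, fell in NOD nodes at both younger ages. Reg2 (chromosome 6, 78357959 to 78358018) was at -2.55 ± 1.21 (SD, n = 6; adjusted p = 0.00505) at 10 days and -2.40 ± 1.029 (n = 6; adjusted p = 0.0115) at 4 weeks. Reg3a was at -1.39 ± 0.346 (adjusted p = 0.000836) and -2.30 ± 0.988 (adjusted p = 6.57e-06), and Reg3b at -1.26 ± 0.401 (adjusted p = 0.00505) and -2.81 ± 0.775 (adjusted p = 3.35e-06). Each of the 3 genes lay under the pool on every array of both ages. All 6 calls stood with the 2% span and with the scanner ratio. Under scale normalisation between arrays Reg2 was not called at 10 days (-1.78, adjusted p = 0.157) or 4 weeks (-2.01, adjusted p = 0.119), nor was Reg3b at 10 days (-0.89, adjusted p = 0.115).

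Some genes rose at both younger ages. Cadm4, a cell adhesion molecule (chromosome 7, 25289084 to 25289143), was at 0.89 ± 0.181 at 10 days (6 of 6 arrays; adjusted p = 8.44e-06) and 0.87 ± 0.128 at 4 weeks (6 of 6; adjusted p = 7.57e-06). At 12 weeks Cadm4 was at 0.745 ± 0.451 (4 of 5 arrays; adjusted p = 0.00813), a value outside the rule for that age and chosen after it was seen. Trim55, a RING finger protein of striated muscle, was at 1.14 ± 0.332 and 1.65 at 10 days and 4 weeks. Pdpk1, the kinase that activates Akt (chromosome 17, 24243816 to 24243875), was at 1.01 ± 0.238 and 2.29 (1.59 with the 2% span), and both genes were above the pool on every array of those ages. The RNA helicase Ddx25 was at 1.02 and 2.86 (1.27 with the 2% span). In all, 24 genes were called higher at both ages, against 1.99 expected if the calls were independent, and 8 genes lower against 0.534. Genes called at both ages share the same strains and the same dye orientation, so the overlap does not separate a strain difference from a dye effect.

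**Figure D1:**
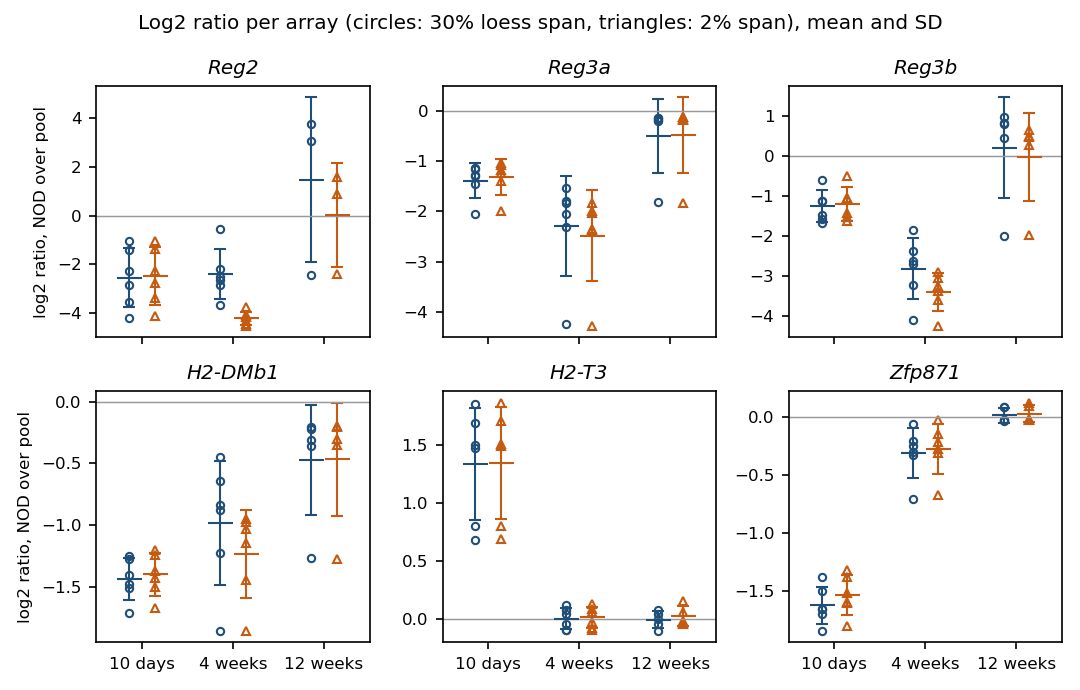
Log2 ratio of NOD over the NOD.B10 pool (y axis) for Reg2, Reg3a, Reg3b, H2-DMb1, H2-T3 and Zfp871 on each array, by age (x axis), with the 30% span as circles, the 2% span as triangles, and the mean with its SD. The Reg genes lay below 0 at 10 days and 4 weeks in the mean, and H2-T3 was at 1.33 at 10 days and above background in neither channel at 4 weeks.

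At 10 days the lowest genes with the same sign on all 6 arrays, besides Reg, lay largely on chromosome 17. D17H6S56E-5 (35134128 to 35134187) was at -2.42 ± 0.215 (adjusted p = 5.13e-12). The zinc finger gene Zfp871 (32910629 to 32910688) was at -1.62 ± 0.16 (adjusted p = 1.5e-11). H2-DMb1, a chain of the chaperone that loads peptides on class II, was at -1.44 ± 0.169 (adjusted p = 2.37e-06). Vars, the valyl-tRNA synthetase, was at -1.18 ± 0.287 (adjusted p = 1.13e-07), and Zfand3 at -1.15 ± 0.183 (adjusted p = 1.27e-09). Several class I genes were also lower, H2-Q8 at -1.12 ± 0.128 (adjusted p = 4.04e-09), H2-T22 at -0.765 and H2-Q4 at -0.694. Gpr182, a receptor of endothelium, was at -1.15. In the other direction H2-T3, a class I gene with a product found in gut epithelium and activated T cells, was at least 2.52-fold higher in NOD (1.33 ± 0.479; adjusted p = 2.66e-07), since the pool was not above background on any array. The kinase gene Sik1 rose to 1.31 ± 0.33 (adjusted p = 4.15e-08). Clic5 rose to 0.86 ± 0.437, and Slc14a2, H3f3a and Rps14 to 0.88, 0.84 and 0.83.

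The H2 region (34063096 to 37157466 of chromosome 17) held 147 tested genes, and 15 of them were called at 10 days, 3 higher and 12 lower. That was 10.2% against 1.01% of genes elsewhere (odds ratio 11.1, Fisher's exact p = 6.67e-11). Over the whole of chromosome 17, 32 of 934 genes were called, 9 higher and 23 lower (odds ratio 3.65, adjusted exact p = 1.49e-07). Without 10-day array 5 the odds ratio for called genes on chromosome 17 at 10 days was 2.35 (adjusted exact p = 0.000795) and that of the H2 region 7.4. At 4 weeks 12 genes of the region were called, 7 higher and 5 lower (odds ratio 3.33, exact p = 0.00054), and with the 2% span 14 genes, 1 higher and 13 lower (odds ratio 9.68, exact p = 1.45e-09). With the scanner ratio the region's odds ratio was 1.79 (exact p = 0.0153) at 10 days and 1.23 (exact p = 0.233) at 4 weeks. Chromosome 17 as a whole was not enriched at 4 weeks with the 30% span (36 genes; odds ratio 1.51, adjusted exact p = 0.402), and was with the 2% span (odds ratio 2.56, adjusted exact p = 0.00177). Probes of the same gene differed. At 10 days the 4 probes of H2-K1 were at -2.46, -1.39, 0.40 and 0.41. Those of H2-Aa ranged from -2.17 to 0.20, and the other probe of H2-DMb1 was at -0.02. The 2 probes of D17H6S56E-5 (-2.45 and -2.42) and those of Vars (-1.18 and -1.09) lay close together. A value in this region therefore belongs to a probe, and NOD and NOD.B10 by name differ in the sequence of this region.

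**Figure D2:**
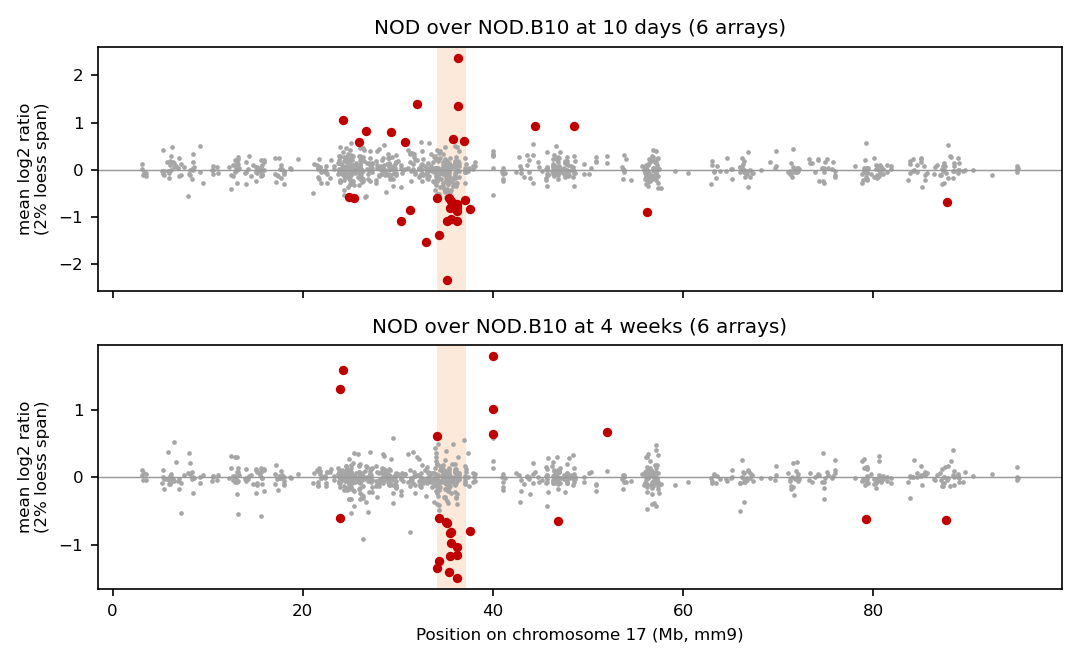
Mean log2 ratio of NOD over NOD.B10 with the 2% span (y axis) for the tested genes of chromosome 17 by position in Mb (x axis, mm9), at 10 days and 4 weeks, with called genes in red and the H2 region shaded. In the H2 region 17 genes were called at 10 days and 14 at 4 weeks with this span.

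Reticular and blood endothelial genes were lower on 5 of 6 arrays at 10 days. Array 5 stood apart, with medians of 0.30 for reticular (others -0.53 to -0.31), 0.77 for fat (others -0.37 to -0.18) and 0.043 for blood endothelial genes (others -0.323 to -0.148). Of 41 reticular and fibroblast genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), and the list median was -0.234 (adjusted p = 0.00178; adjusted p = 0.686 with an estimated correlation). Among them the smooth muscle genes Cnn1, a calponin, and Myh11, a myosin, were at -2.05 ± 1.869 and -1.59 ± 1.259, each under the pool on 5 of 6 arrays. Desmin (Des) was at -0.83 ± 0.245 and biglycan (Bgn) at -0.73 ± 0.304, each on 6 of 6. The called gene that rose was the chemokine Ccl19 (0.605, and 0.173 with the 2% span, not called). Blood endothelial genes had a median of -0.16 (adjusted p = 0.00178; adjusted p = 0.562 with an estimated correlation), with 0 of 31 called singly over all genes tested and 0 adjusted over the list alone (limma). Lymphatic genes had a median of -0.164 (adjusted p = 0.0387; adjusted p = 0.619 with an estimated correlation), and 1 of 20, Stab1, was called at -0.64. The lymphatic call ended without 10-day array 2 (adjusted p = 0.0674) or 4 (adjusted p = 0.2). Fat markers were not called as a list (median -0.107, adjusted p = 0.12). Of 29 members 4 were called lower, among them Cfd at -1.63 ± 1.523 and Car3 at -1.11 ± 1.577, each on 5 of 6 arrays. The SD of Car3 exceeded its mean, and those of Cfd, Cnn1 and Myh11 were large beside theirs. The model shares a single spread over the ages, so these calls may rest on p-values that are too small. The exocrine list had a median of -0.305 (adjusted p = 0.858) with per-array medians from -3.75 to 1.69, and its 3 called members were the Reg genes.

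Among immune lists at 10 days, T cell genes had a median of 0.07 (adjusted p = 0.00483; adjusted p = 0.686 with an estimated correlation). The T cell receptor chain gene Cd247 rose to 0.674 (adjusted p = 4.07e-05) and the transcription factor Ets1 to 0.639. The interleukin 7 receptor gene Il7r fell to -0.59 (adjusted p = 0.000347). The T cell call ended without 10-day array 3 (median -0.02, adjusted p = 0.145), and array 5 had a T cell median of -0.253 where the others had 0.01 to 0.415. Macrophage genes were lower (-0.13, adjusted p = 0.00483; adjusted p = 0.619 with an estimated correlation), with 0 of 39 called by limma and 0 adjusted over the list alone. Granulocyte genes (-0.168, adjusted p = 0.00178; adjusted p = 0.562 with an estimated correlation) were lower with 1 of 32 called, the protease inhibitor Stfa1 at -0.629. Lymphoid progenitor genes (-0.131, adjusted p = 0.00693; adjusted p = 0.0876 with an estimated correlation) were lower with 1 of 21 called, Il7r. Type I interferon genes had a median of 0.047 (adjusted p = 0.0387; adjusted p = 0.79 with an estimated correlation; 0 of 41 called by limma). It was under 0 on 4 of 6 arrays and at 0.231 and 0.366 on arrays 2 and 6. The call ended without 10-day array 2 (median 0, adjusted p = 0.212) or 6 (median 0.02, adjusted p = 0.633). Genes for peripheral tissue antigens, which lymph node stroma can express, had a median of 0.166 (adjusted p = 0.00181; adjusted p = 0.562 with an estimated correlation). The called member of 26 was albumin (Alb), at 1.09 ± 1.519 on 5 of 6 arrays. Its SD exceeded its mean, so with a single spread shared over the ages this call may rest on a p-value that is too small. Aire, which drives such antigens, was at -0.60 (adjusted p = 3.83e-05), and -0.537 with the 2% span, under 1.5-fold. Ribosomal protein genes had a median of 0.355 (adjusted p = 0.00178; adjusted p = 0.686 with an estimated correlation), which was 0.015 (adjusted p = 0.958) with the 2% span. Of single genes, Chgb, a granin of endocrine cells, was at 0.885 (adjusted p = 0.00128), the cytokine signalling inhibitor Socs1 at 0.80 (adjusted p = 0.000384) and the phosphatase gene Dusp1 at 0.74. Lower were the proliferation marker Mki67 at -0.72, the dendritic cell gene Fscn1 at -0.69 and the chemokine Ccl5 at -0.65. With the scanner ratio Cd247, Ets1, Il7r, Chgb, Socs1, Fscn1, Stab1, H3f3a and Slc14a2 were not called (adjusted p = 0.07 to 0.235), nor were Rps14 (0.331) and Il7r (-0.529) with the 2% span. The H2 class I list, with 1 member called higher and 4 lower of 16, had a median of -0.341 (adjusted p = 0.112), and -0.46 (adjusted p = 7.92e-05; adjusted p = 0.208 with an estimated correlation) with the 2% span.

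In all, 212 of 19344 genes were called at 10 days, 89 higher and 123 lower (42% higher). With the 2% span it was 114 higher and 102 lower (52.8%), of which 75 and 91 were shared, and with the scanner ratio 322 higher and 1515 lower (17.5%). The scanner ratios were not centred on 0: their medians per array went down to -0.104 at 10 days and -0.346 at 4 weeks. At 12 weeks these medians were 0 on every array, and the scanner ratio still called 209 genes higher and 3819 lower. The lack of centring therefore does not account for the excess of lower calls at that age. Without 10-day array 5 the count was 308.

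At 4 weeks fat genes were higher in NOD nodes than in the NOD.B10 pool. There was 1 pool at that age, and an unusual pool could give the same values on every array. Fabp4, the fatty acid carrier of adipocytes, was at 2.98 ± 0.683 (6 of 6 arrays; adjusted p = 1.97e-06), adipsin (Cfd) at 2.59 ± 0.47 (adjusted p = 2.84e-05), Car3 at 1.54 ± 0.434 (adjusted p = 0.00477) and fatty acid synthase (Fasn) at 1.03 ± 0.237 (adjusted p = 5.53e-07). With the 2% span these values were 1.53, 1.24, 1.33 and 0.72, and all stayed called, while with the scanner ratio Cfd was not (adjusted p = 0.0852). Of 29 fat markers 6 rose and 0 fell (7 and 0 adjusted over the list alone; limma). The list median was 0.18 (adjusted p = 5.16e-05). The call held with the 2% span (0.249, adjusted p = 5.67e-05) and the scanner ratio (adjusted p = 2.58e-05), but not with an estimated correlation (adjusted p = 0.73 with an estimated correlation). Decorin (Dcn), a matrix proteoglycan, was at 2.77, and 1.05 with the 2% span, Thy1 at 1.66 and 0.87, and Tagln at 1.42 and 0.92. Glycam1, a mucin of high endothelial venules, was at 2.03 ± 0.615 (adjusted p = 8.31e-08) and 0.61. The reticular list, with 7 of 41 higher and 0 lower over all genes and over the list alone (limma), had a median of 0.034 (adjusted p = 0.00103; adjusted p = 0.884 with an estimated correlation), and adjusted p = 0.0784 with the 2% span. The B cell gene Ms4a1 was at 0.91 and the antibody joining chain gene Jchain at 0.98, with the B cell list not called (median -0.018, adjusted p = 0.217).

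Among the lowest genes at 4 weeks besides the Reg family were Cuzd1 at -1.07, H2-DMb1 at -0.98 ± 0.503 (adjusted p = 8.21e-05), the alanine aminotransferase Gpt at -0.98 ± 0.207 (adjusted p = 8.31e-08) and H2-T22 at -0.95 ± 0.42 (adjusted p = 1.55e-05). Also lower were the glutaminase Gls2 at -0.92, Zfpm1 at -0.91 and Reg3d at -1.01, and all of these lay under the pool on 6 of 6 arrays. The Reg3d call ended without 4-week array 1 (-0.86, adjusted p = 0.0529). D17H6S56E-5 was at least 1.76-fold lower, since NOD was not above background. The class I list had a median of -0.112 (adjusted p = 0.701), and -0.525 (adjusted p = 1.58e-13; adjusted p = 0.000606 with an estimated correlation) with the 2% span, where 8 members were called lower. Among them H2-D1, a classical class I heavy chain, was at -0.18 (adjusted p = 0.683), and -1.39 (adjusted p = 1.52e-07) with the 2% span. H2-K1, also a classical heavy chain, was called higher at 1.976 (adjusted p = 2.86e-06). It was not called with the 2% span (-0.034, adjusted p = 0.849) or the scanner ratio (0.104, adjusted p = 0.532).

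Among the highest genes at 4 weeks were the 18S ribosomal RNA Rn18s at 5.88, the mitochondrial leucyl-tRNA synthetase gene Lars2 at 4.44, the pancreatic protease genes Ctrc at 4.24 and Cpa1 at 3.58, and Ptprz1 at 4.16. They also included granulin (Grn) at 4.09, Rplp1 at 4.09, Rps18 at 3.72, Rpl37a at 3.47 and Lrrc58 at 3.36. With the 2% span Rn18s was at 1.79, Rplp1 at 1.16, Lars2 at 1.12, Lrrc58 at 0.94, Grn at 0.81 and Rps18 at 0.605, while Ctrc, Ptprz1, Cpa1 and Rpl37a were not called. Of 42 ribosomal protein genes 33 were called higher and 1 lower, the same counts adjusted over the list alone. Their median was 1.756 (adjusted p = 8.95e-38; adjusted p = 0.0204 with an estimated correlation), and -0.049 (adjusted p = 0.0873) with the 2% span. Of 33 exocrine genes 14 were called higher and 4 lower (19 and 4 adjusted over the list alone). Their median was 2.092 (adjusted p = 3.65e-05; adjusted p = 0.886 with an estimated correlation), and turned to -0.508, lower, with the 2% span (adjusted p = 3.95e-05). Oxidative phosphorylation genes (median 0.072, 8 of 38 higher, adjusted p = 0.042; adjusted p = 0.73 with an estimated correlation) lost their call with the 2% span (median -0.041, adjusted p = 0.146). The median ratio of the 50 brightest probes of each array was 1.64 to 4.7 on the 4-week arrays, and -0.09 to 0.5 with the 2% span. The Deaf1 and translation list was lower (median -0.163, 2 of 31 higher and 1 lower; adjusted p = 0.042; adjusted p = 0.51 with an estimated correlation), and also with the 2% span (-0.144, adjusted p = 3.95e-05; adjusted p = 0.000606 with an estimated correlation). Single arrays ended both of these weak calls. Without 4-week array 1 the Deaf1 and translation list had adjusted p = 0.132. Without 4-week array 5 oxidative phosphorylation had adjusted p = 0.12.

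In all, 516 genes were called at 4 weeks, 432 higher and 84 lower (83.7% higher). The 2% span gave 130 higher and 94 lower (58%), with 98 and 39 shared, and the scanner ratio 535 higher and 4932 lower (9.79%).

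At 12 weeks few genes passed. Tfam, the mitochondrial transcription factor (chromosome 10, 70688212 to 70688232), rose to 0.66 ± 0.067 (SD, n = 5; adjusted p = 0.0128). Khsrp, a KH-type splicing regulator (chromosome 17, 57160973 to 57161032), rose to 0.63 ± 0.273 (adjusted p = 0.0067). Each was higher on 5 of 5 arrays and was called with the 2% span (0.67 and 0.65) and the scanner ratio. Rps20 at 1.53 (adjusted p = 0.0225), Rpl27 at 1.44 (adjusted p = 0.0305) and the bicarbonate transporter gene Slc4a7 at 1.03 (adjusted p = 0.0225) were also above the pool on 5 of 5 arrays. None of these 3 was called with the 2% span. Ribosomal protein genes were higher (median 0.111, 2 of 42 called and 12 adjusted over the list alone; adjusted p = 4.8e-19; adjusted p = 0.246 with an estimated correlation), with array 1 at -0.043. With the scanner ratio the list turned to -0.25 (adjusted p = 0.547) and lay below 0 on all 5 arrays (-0.217 to -0.036). With the 30% span the 50 brightest probes of an array had a median ratio of up to 1.91. Oxidative phosphorylation genes were lower (median -0.048, 0 of 38 called by limma; adjusted p = 0.000116; adjusted p = 0.203 with an estimated correlation). In all, 12 genes were called, 12 higher and 0 lower (limma; 261 at an unadjusted p). There were 18 with the 2% span (15 higher and 3 lower, 83.3%) and 4028 with the scanner ratio (209 higher and 3819 lower, 5.19%). In the H2 region 0 genes were called (limma, of 147). The count was 2 without 12-week array 3 or 7, 3 without 4, 4 without 6 and 33 without 1. Each of the 5 genes named lost its call without at least 1 array. Tfam had adjusted p = 0.119 without array 7, Khsrp fell to 0.53, under 1.5-fold, without array 1. Rps20, Rpl27 and Slc4a7 had adjusted p = 0.24, 0.26 and 0.247 without array 3.

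From 10 days to 4 weeks the NOD over NOD.B10 contrast of fat and stromal genes rose. Cfd moved by 4.22 log2 (adjusted p = 2.13e-05; 2.80 with the 2% span), Fabp4 by 3.18, Car3 by 2.65, Dcn by 3.08, Cnn1 by 2.20 and the collagen gene Col1a2 by 1.74. Fabp4 moved by 1.75, Car3 by 2.36, Dcn by 1.44, Cnn1 by 2.26 and Col1a2 by 1.26 with the 2% span, all still called, and with the scanner ratio Col1a2 was not (adjusted p = 0.111). The fat list rose by a median of 0.36 (8 of 29 called, 10 adjusted over the list alone; adjusted p = 7.31e-05; adjusted p = 0.677 with an estimated correlation). The reticular list rose by 0.413 (13 of 41, the same over the list alone; adjusted p = 6.8e-08; adjusted p = 0.388 with an estimated correlation) and blood endothelial genes by 0.239 (adjusted p = 0.000166; adjusted p = 0.388 with an estimated correlation), with Pecam1 up by 0.77. Lymphoid progenitor genes rose by 0.121 (adjusted p = 0.00465; adjusted p = 0.0393 with an estimated correlation, and 0.0744 with that and the 2% span). Reg3b fell further by 1.55 (adjusted p = 0.0153), though not with the scanner ratio (adjusted p = 0.302). Hnrnpdl fell by 1.32 (adjusted p = 2.86e-06), Tmem184a by 1.25 and Tmem97 by 1.23. The T cell genes Ets1 and Cd247 fell by 0.81 and 0.75, Ly6a by 0.94 and the interferon-induced gene Ifit3 by 0.72. The T cell list fell by 0.217 (adjusted p = 0.0135; adjusted p = 0.703 with an estimated correlation). The type I interferon list fell by 0.138 (adjusted p = 0.0235; adjusted p = 0.703 with an estimated correlation). At 4 weeks itself the mean list medians were 0.01 for blood endothelial, -0.014 for lymphoid progenitor, -0.051 for T cell and -0.056 for interferon genes. At that age 10778 of 19344 genes were above background in NOD on no array, and absent signal also gives a ratio near 0. Rn18s (6.11), Ctrc (4.36), Lars2 (4.11) and Cpa1 (3.99) also rose, but with the 2% span these were 2.32, 1.23, 1.15 and 0.94, and Ctrc and Cpa1 were not called (adjusted p = 0.479 and 0.473). The Ctrc call ended without 10-day array 1 (adjusted p = 0.052) or 4-week array 6 (0.0578) or 7 (0.0621). The ribosomal list rose by 1.589 (adjusted p = 3.32e-13; adjusted p = 0.388 with an estimated correlation) and the exocrine list by 2.314 (adjusted p = 0.00817; adjusted p = 0.703 with an estimated correlation). With the 2% span these list medians were -0.05 and -0.298 and not called. The exocrine call also ended without 10-day array 1 (1.49, adjusted p = 0.119) or 3 (adjusted p = 0.0535). The T cell call ended without 10-day array 3 (adjusted p = 0.0816), and the interferon call ended without 10-day array 2 (adjusted p = 0.11) or 6 (adjusted p = 0.274). Insulin 2 (Ins2) was up by 1.97 (adjusted p = 0.0346), and by 0.56 with the 2% span, not called. That call also ended without any of 10-day arrays 1, 3 and 5 and 4-week arrays 3, 5, 6 and 7 (adjusted p = 0.0556 to 0.0858). In all, 843 genes were called, 549 higher and 294 lower (65.1% higher). It was 307 and 271 (53.1%) with the 2% span and 952 and 3249 (22.7%) with the scanner ratio. All 10-day arrays shared a scan and a software version that no later array had, so age and scan cannot be told apart in the differences from 10 days. Each age also had its own single pool, so age and pool cannot be told apart either.

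Between 10 days and 12 weeks the lysozyme gene Lyz2 rose by 1.60 (adjusted p = 0.0329), Mfge8 by 1.30 (adjusted p = 0.0463) and Reg2 by 4.01 (adjusted p = 0.0252; 3 arrays at 12 weeks), while Serf2 fell by 0.81. On 12-week array 1, the array with the most Cy5 signal at that age, Reg2 was at -2.42. Its rise came from the other arrays with a value, where Cy5 signal was weak. D17H6S56E-5, Zfp871, Myh11, H2-T3, Sik1, Clic5 and Cd8a were also called, but at 12 weeks NOD was above background on 0 of 5 arrays for each, so the size of their change was not measured. Reticular (0.276, adjusted p = 0.00112; adjusted p = 0.57 with an estimated correlation) and blood endothelial lists (0.193, adjusted p = 0.00158; adjusted p = 0.57 with an estimated correlation) rose, but with the scanner ratio the blood endothelial list turned to -0.23 (adjusted p = 0.761). The T cell list fell by 0.075 (adjusted p = 0.00526; adjusted p = 0.82 with an estimated correlation), a call lost without 10-day array 3 (adjusted p = 0.119). Since most genes were below background in NOD at 12 weeks, a ratio near 0 there is also what absent signal gives. Lyz2 and Mfge8 each lost their call without any of several arrays (adjusted p = 0.0796 and 0.0912 without 12-week array 6). In all, 179 genes were called, 118 higher and 61 lower (65.9%), of which 19 (14 higher, 5 lower) were measured in both channels at both ages. It was 94 and 97 (49.2%) with the 2% span, 1162 and 3122 (27.1%) with the scanner ratio, and 306 without 10-day array 5.

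From 4 to 12 weeks the NOD over NOD.B10 contrast of fat genes fell again, Fabp4 by 2.96 (adjusted p = 0.000702; 1.56 with the 2% span) and Cfd by 2.84. The fat list fell by 0.172 (adjusted p = 3.01e-05; adjusted p = 0.877 with an estimated correlation). At 12 weeks 349 of 19344 genes were above background in NOD on at least 0.5 of the arrays. A list median near 0 at that age is therefore also what absent signal gives. Age and pool cannot be told apart in this difference either. Reg3b rose by 3.02 (adjusted p = 0.000611) and Reg2 by 3.86 (adjusted p = 0.0434), but not on 12-week array 1, the array with the most Cy5 signal at that age. There Reg3b was at -2.01 (others 0.46 to 0.99) and Reg2 at -2.42 (3.07 and 3.73 on the other 2 with a value). Reg3a was also called, but at 12 weeks NOD was not above background, so its change was not measured. Gpt rose by 0.98, Zfpm1 by 0.88 and H2-T22 by 0.88, each with NOD above background on 1 of 5 arrays at 12 weeks. With the scanner ratio H2-T22 turned to -1.17 (adjusted p = 0.00395) and Zfpm1 to -0.16 (adjusted p = 0.79), and Gpt was not called (adjusted p = 0.471). Lars2 (-3.26), Rpl34 (-2.46), Rpl9 (-2.42) and Thy1 (-1.76) fell. Of 42 ribosomal genes 22 fell and 1 rose (28 and 1 adjusted over the list alone). Their list fell by 1.193 (adjusted p = 2.9e-28; adjusted p = 0.101 with an estimated correlation), and turned to 0.171, higher, with the 2% span (adjusted p = 0.00131). The exocrine list fell by 0.905 (adjusted p = 0.0131; adjusted p = 0.982 with an estimated correlation) and turned to 0.602 with the 2% span (adjusted p = 0.00193). It lost its call without 12-week array 1 (-0.21, adjusted p = 0.661), 4-week array 5 (-0.55, adjusted p = 0.158) or 4-week array 7 (-0.76, adjusted p = 0.0858). In all, 390 genes were called, 73 higher and 317 lower (18.7% higher), of which 179 (5 higher, 174 lower) were measured in both channels at both ages. It was 88 and 85 (50.9%) with the 2% span and 3267 and 3119 (51.2%) with the scanner ratio. Slides 3 and 5 held an array of each age. With slide as a fixed block 108 genes were called, 69 higher and 39 lower. Fabp4, Cfd, Lars2 and Gpt stayed called in the same direction, while Zfpm1 (adjusted p = 0.08), H2-T22 (0.193), Rpl34 (0.0698) and Rpl9 (0.108) did not. The list medians were then -0.25 for fat, -1.21 for ribosomal and -1.53 for exocrine genes. Within slide 3 the fat median was 0.469 at 4 weeks and 0.022 at 12 weeks, the ribosomal median 0.687 and -0.043, and the exocrine median 0.436 and -0.763. Within slide 5 these were 0.163 and -0.013, 2.07 and 0.101, and 2.91 and 0.457. On the arrays of scan 3 alone the genes called 12 weeks minus 4 weeks numbered 491, and the exocrine list was not (-0.45, adjusted p = 0.103).

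Deaf1, a transcription factor that regulates tissue antigens in lymph node stroma, was not called at any age (0.13, -0.20 and -0.12 at 10 days, 4 weeks and 12 weeks). Nor were the splicing regulators Ptbp2 (-0.05 at 10 days, with no NOD signal above background later) and Srsf10 (-0.31, 0.27 and -0.07), the translation factor gene Eif4g3 (-0.49, 0.04 and 0.03), the adenosine receptor Adora1 (0.12, -0.24 and -0.12), Ins1 (-0.38, -0.71 and 0.10) or Ins2 (-0.81, 1.16 and 0.01). At 12 weeks NOD was above background on at most 1 of 5 arrays for each of these genes but Ins2, so a value near 0 there does not show equal expression. Without 10-day array 6 Ins2 was called lower at 10 days (-1.23, adjusted p = 0.0481). Splicing factors as a list (54 genes) had medians of -0.055, -0.029 and 0.003 with adjusted p = 0.858, 0.63 and 0.981.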

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

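The tests of brightness, of the Reg genes and of the H2 probes, and the 2% span, were chosen after the results were seen, while the regrouping of the arrays by age was fixed before.

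Ribosomal and exocrine genes were higher at 4 weeks with the 30% span and not with the 2% span. Set against equally bright genes outside both lists, ribosomal genes differed by -0.11 ± 0.11 log2 (SD over 6 arrays) and exocrine genes by -0.64 ± 0.37, while the list means themselves were 1.65 and 1.86. These values are consistent with a trend with brightness that the wide loess curve left in place, and the test could have come out the other way. Dye bias stays open, since 0 arrays had the dyes swapped. No biological difference in these lists is needed for the pattern, and a true difference with age in them was not excluded.

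The Reg genes were lower at 10 days and 4 weeks. The Reg median lay more than 1 log2 under the exocrine median on 10 of the 12 arrays with both spans. The exceptions were 10-day arrays 1 and 3, with exocrine medians of -3.75 and -3.44. The Reg genes were picked for being low on every array, so the count of 10 cannot decide on less exocrine tissue in NOD. On 10-day arrays 2, 4, 5 and 6 the exocrine median was positive (0.46 to 1.78, and 0.2 to 1.6 with the 2% span). Less exocrine tissue is argued against on those arrays only. At 4 weeks the exocrine median changed sign with the span (0.98 to 3.91, against -0.86 to -0.07). Less exocrine tissue stays open there and on 10-day arrays 1 and 3. The 6 calls stood under 9 of 10 other scalings, which reached the limit set against scaling as the cause. Of these, Aquantile normalisation could not change the ratios, and the scanner ratio and the submitted table gave the same means. Median centring called nearly all of its genes lower, so the lower calls that stood there carry no weight. The count of 9 therefore cannot decide on scaling. Scale normalisation between arrays ended 3 of the calls, and scaling stays open for those. Reg3a at both ages and Reg3b at 4 weeks stayed called under it (-0.97, -2.08 and -2.56). For these calls scaling is argued against as the whole cause. The control stays open, because there was 1 pool per age and an unusual pool could give the same values. A strain difference in the expression of these genes may also account for the pattern and was tested only through these ratios. By name the strains differ in the H2 region, and Reg2 lies on another chromosome.

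Probes of the same gene gave different values in the H2 region at 10 days. Strain variants under single probes and signal shared between class I genes cannot be told apart from a difference in expression by these values. The median range between probes was 0.7 in 6 genes with any called probe and every probe placed in the H2 region, against 0.65 in 89 other genes with any called probe, above 71.5% of 10000 random sets. That definition left H2-K1 and H2-Ab1 among the others, because each has a probe without a position, and a wider one, made after the value was seen, took genes with any probe in the region and gave 1.1 against 0.64, above 100% of sets, which may reflect strain variants but was the second attempt. Probes more than 1 log2 and 2 standard errors apart were found in 2 genes outside class I (H2-Aa and H2-DMb1) and 0 within it by the first definition, and in 3 (H2-Ab1 too) and 1 (H2-K1) by the wider one, so only the wider one reached the 3 set against shared signal.

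The number of genes called 4 weeks minus 10 days was 843, a tested difference between ages. Of 100 splits of these arrays, the real one included, 1 gave as many. The highest of the others, which moved 1 array of each age, gave 493, which argues against a random grouping of the arrays. For 12 weeks minus 10 days the count was 179, again reached by 1 of 100 splits, with 48 as the highest other. For 12 weeks minus 4 weeks it was 390, reached by 1 of 100, with 125 as the highest other. Splits exclude chance only. The arrays of an age shared a single pool, so the splits cannot separate age from pool in any of these differences. All 10-day arrays were scanned apart from the rest, so scan and age cannot be told apart there. With slide as a fixed block 108 genes were called 12 weeks minus 4 weeks.

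Several gene lists differed between ages by the test of the difference. At 4 weeks minus 10 days the list medians were 2.31 for exocrine, 1.59 for ribosomal, 0.41 for reticular, 0.36 for fat, 0.24 for blood endothelial, 0.14 for macrophage, 0.12 for lymphoid progenitor, 0.11 for lymphatic and 0.11 for granulocyte genes. They were -0.14 for peripheral tissue antigens, -0.14 for type I interferon and -0.22 for T cell genes. At 4 weeks itself the mean list medians were 0.006 for lymphatic, 0.01 for blood endothelial and 0.004 for peripheral tissue antigen genes. They were -0.014 for lymphoid progenitor, -0.037 for macrophage and -0.044 for granulocyte genes. At that age 10778 of 19344 genes were above background in NOD on no array, and absent signal also gives a ratio near 0. At 12 weeks minus 10 days they were 0.28 for reticular, 0.19 for blood endothelial, 0.15 for lymphoid progenitor, 0.13 for macrophage and 0.11 for granulocyte genes, and -0.07 for T cell and -0.17 for peripheral tissue antigen genes. At 12 weeks minus 4 weeks they were -1.19 for ribosomal, -0.91 for exocrine, -0.17 for fat, -0.07 for oxidative phosphorylation and -0.03 for reticular genes. With the 2% span, 12 weeks minus 4 weeks turned to 0.17 for ribosomal and 0.6 for exocrine genes, and the exocrine, ribosomal, macrophage and peripheral tissue antigen lists at 4 weeks minus 10 days and the reticular and oxidative phosphorylation lists at 12 weeks minus 4 weeks were not called. With the scanner ratio 2 of the 12 calls at 4 weeks minus 10 days were kept, 1 of 7 at 12 weeks minus 10 days and 3 of 5 at 12 weeks minus 4 weeks. Single arrays ended several calls at 4 weeks minus 10 days: peripheral tissue antigens without 10-day array 1 (adjusted p = 0.153), macrophage genes without 10-day array 2 or 4 (0.108, 0.14), granulocyte genes without the same arrays (0.127, 0.121) and lymphatic genes without 10-day array 4 (0.0585). The calls of peripheral tissue antigens, macrophage and granulocyte genes each also ended without some other arrays (0.051 to 0.0572). At 12 weeks minus 10 days the granulocyte call ended without 10-day array 2 (0.0822) or 4 (0.0592) the macrophage call without array 4 (0.0541) and the T cell call without array 3 (0.119). With an estimated correlation only the lymphoid progenitor list at 4 weeks minus 10 days stayed called (adjusted p = 0.0393). With that and the 2% span it was not (adjusted p = 0.0744), and the class I list at 12 weeks minus 4 weeks (0.65, adjusted p = 8.26e-05) was the only list called in a difference between ages.

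Single arrays stood apart in 16 of 174 groups tested (9.2%), by their gap to the other arrays of the age. The limit is meant to pick about 1 in 20 groups by chance when values are normally distributed, and that rate was not tested here. At 10 days array 5 had a reticular median of 0.3 (others -0.53 to -0.31) and a fat median of 0.77 (others -0.37 to -0.18), and was the only one with a T cell median under 0 (-0.25). Array 1 had Reg3a at -2.06 (others -1.45 to -1.13), and array 4 had Deaf1 at 0.74 (others -0.19 to 0.15). At 4 weeks array 1 stood apart in 6 groups: class I at -1 (others -0.19 to 0.04), class II at -0.37 (others 0 to 0.02), macrophage at -0.17 (others -0.03 to 0.01), dendritic at -0.07 (others -0.01 to 0.02), Reg3a at -4.24 (others -2.31 to -1.53) and Ptbp2 at -0.53 (others -0.18 to -0.04). Array 5 had a Deaf1 and translation median of -0.07 (others -0.23 to -0.18). Over all genes 12-week array 1 correlated with the other 12-week arrays at 0.044 to 0.07, against 0.482 to 0.626 among those. It had a reticular median of 0.08 (others 0 to 0.01), an oxidative phosphorylation median of -0.14 (others -0.04 to -0.01), Rps20 at 0.11 (others 1.5 to 2.06) and Ins2 at 0.63 (others -0.17 to -0.12), and array 6 had Srsf10 at -0.2 (others -0.06 to -0.01).

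Spike-in control spots, which no comparison used, were above background in Cy5 for 18.4% of 320 spots on the weakest 12-week array. The Cy5 share was 18.4% to 24.7% on 12-week arrays 3, 4, 6 and 7 and 80.3% on 12-week array 1. It was 73.4% to 89.7% at 4 weeks and 97.8% to 100% at 10 days. In Cy3 the share was 86.2% to 90.9% at 12 weeks and 100% on every array of the earlier ages.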

How the results depend on the processing

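The loess spans of 5%, 2% and 1%, the limit to genes measured in both channels, the fit without slide 3, the fit without 10-day arrays 1 and 3 and the fit of scan 3 alone were chosen after the data were seen, and every other alternative before. Signal was lowest at 12 weeks, with 220 of 19344 genes above background in Cy5 on every 12-week array against 11812 on every 10-day array. The main counts were 212 (89 higher) at 10 days, 516 (432 higher) at 4 weeks and 12 (12 higher) at 12 weeks. Between ages they were 843 (549 higher), 179 (118 higher) and 390 (73 higher), in the order 4 weeks minus 10 days, 12 weeks minus 10 days and 12 weeks minus 4 weeks. Of 147 named gene results, 147 kept their direction and side of the threshold with slide or scan as a random block. Aquantile normalisation leaves the log ratios as they are, so it could change none of them. With trend and robust moderation 142 did, with array weights 136, without 10-day arrays 1 and 3 135, and without slide 3 140. Fewer did with scale normalisation (126), the mean of a gene's probes (122, with 14 weaker and 8 reversed), the 2% span (118, with 17 weaker and 7 reversed), the submitted table (93), the scanner ratio (92, with 31 weaker and 10 reversed) and median centring (57). Of 55 list results 55 and 54 kept them with random slide and random scan, but 29 with the 2% span (8 reversed), 28 with the scanner ratio (22 weaker, 4 reversed), 28 with the submitted table and 16 with median centring (19 reversed). The random blocks had estimated correlations of -0.035 for slide and -0.043 for scan. Reg3a stayed lower under every alternative, from -3.27 to -0.97 at 10 days and from -6.85 to -1.91 at 4 weeks. The odds ratio of called genes in the H2 region at 10 days stayed above 1 under every alternative, from 1.35 with median centring to 41.1 with a limit of 2-fold. Below, a result is said to turn where its value or the direction of its list test changed sign, and the H2 region at 12 weeks turned because its main count was 0. Chromosome 17 at 4 weeks was enriched under several alternatives, and outside the omissions of single arrays each odds ratio named for it below had an adjusted exact p of at most 0.0163.

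With the scanner's own ratio, called genes numbered 1837 (322 higher) at 10 days, 5467 (535 higher) at 4 weeks and 4028 (209 higher) at 12 weeks. Between ages the scanner ratio gave 4201 (952 higher) for 4 weeks minus 10 days, 4284 (1162 higher) for 12 weeks minus 10 days and 6386 (3267 higher) for 12 weeks minus 4 weeks. The scanner ratio gave odds ratios of 1.23 for the H2 region at 4 weeks and 1.52 for the H2 region at 12 weeks. Called lists numbered 3 for 4 weeks minus 10 days and 4 for 12 weeks minus 10 days. Exocrine -0.46 at 4 weeks, ribosomal -0.25 at 12 weeks, blood endothelial -0.23 for 12 weeks minus 10 days, Deaf1 and translation -0.43 for 12 weeks minus 4 weeks were the lists that turned with the scanner ratio. H2-Ab1 -0.2 at 4 weeks, Eif4g3 -1.25 and H2-D1 -1.19 at 12 weeks, H2-Ab1 -0.66 for 4 weeks minus 10 days, Eif4g3 -0.87 and Srsf10 -0.89 for 12 weeks minus 10 days were the genes that turned with the scanner ratio. Zfpm1 -0.16, H2-T22 -1.17, Deaf1 -1.3 and H2-K1 0.76 for 12 weeks minus 4 weeks also turned.

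With the submitted value table, called genes numbered 1812 (420 higher) at 10 days, 5765 (903 higher) at 4 weeks and 4036 (205 higher) at 12 weeks. Between ages the submitted table gave 4676 (1392 higher) for 4 weeks minus 10 days, 4171 (1003 higher) for 12 weeks minus 10 days and 6286 (3024 higher) for 12 weeks minus 4 weeks. The submitted table gave odds ratios of 1.18 for the H2 region at 4 weeks and 1.47 for the H2 region at 12 weeks. Called lists numbered 1 at 4 weeks, 4 for 4 weeks minus 10 days and 4 for 12 weeks minus 10 days. Exocrine -0.46 at 4 weeks, ribosomal -0.25 at 12 weeks, blood endothelial -0.27 for 12 weeks minus 10 days, exocrine -0.02 and Deaf1 and translation -0.46 for 12 weeks minus 4 weeks were the lists that turned with the submitted table. H2-Ab1 -0.2 at 4 weeks, Eif4g3 -1.25 and H2-D1 -1.19 at 12 weeks, H2-Ab1 -0.66 for 4 weeks minus 10 days, Eif4g3 -0.87 and Srsf10 -0.89 for 12 weeks minus 10 days were the genes that turned with the submitted table. Zfpm1 -0.16, H2-T22 -1.17, Deaf1 -1.3 and H2-K1 0.76 for 12 weeks minus 4 weeks also turned. The cause was not tested for either.

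With median centring in place of loess, called genes numbered 12102 (334 higher) at 10 days, 11599 (1 higher) at 4 weeks and 745 (0 higher) at 12 weeks. Between ages the median centring gave 8313 (840 higher) for 4 weeks minus 10 days, 11153 (10727 higher) for 12 weeks minus 10 days and 11499 (11498 higher) for 12 weeks minus 4 weeks. The median centring gave odds ratios of 1.35 for the H2 region at 10 days, 2.67 for the H2 region at 12 weeks, 1.12 for chromosome 17 at 10 days and 1.26 for chromosome 17 at 4 weeks. Called lists numbered 17 at 4 weeks, 13 at 12 weeks and 10 for 12 weeks minus 4 weeks. T cell -1.47, type I interferon -1.08 and ribosomal -1.53 at 10 days, exocrine -5.24, reticular -2.9, fat -2.57, ribosomal -4.74 and oxidative phosphorylation -4.13 at 4 weeks, ribosomal -2.61 at 12 weeks were the lists that turned with the median centring. Exocrine -3.34, blood endothelial -0.87, fat -0.96, macrophage -1.05, ribosomal -3.2 and class I -2.96 for 4 weeks minus 10 days, T cell 1.18 for 12 weeks minus 10 days also turned. Reticular 2.61, fat 1.72 and oxidative phosphorylation 2.85 for 12 weeks minus 4 weeks also turned. Sik1 -0.07, Trim55 -0.36, Ddx25 -0.52, Pdpk1 -0.63, Slc14a2 -0.79, Clic5 -0.02, H3f3a -1.01, Rps14 -1.08, H2-K1 -1.48, H2-Aa -1.54, H2-Ab1 -1.25 and H2-Eb1 -1.77 at 10 days were the genes that turned with the median centring. Rn18s -3.19, Lars2 -3.59, Ctrc -3.82, Ptprz1 -4.35, Grn -4.12, Rplp1 -3.51, Rps18 -4.23, Cpa1 -4.56, Rpl37a -4.46, Lrrc58 -3.72, Eif4g3 -4.18, Srsf10 -2.67, Ins2 -4.89, H2-K1 -4.79, H2-Aa -3.6, H2-Ab1 -4.89 and H2-Eb1 -4.37 at 4 weeks also turned. Rps20 -4.07, Rpl27 -4.03, Slc4a7 -3.55, Tfam -0.24, Khsrp -0.77 and H2-K1 -2.59 at 12 weeks also turned. Rn18s -1.09, Ctrc -1.86, Cfd -0.42, Lars2 -2.03, Cpa1 -2.3, Eif4g3 -1.92, Srsf10 -0.91, Ins2 -2.43, H2-K1 -3.31, H2-D1 -3.85, H2-Ab1 -3.63 and H2-Eb1 -2.61 for 4 weeks minus 10 days also turned. Lyz2 -1.32, Mfge8 -2, Sik1 0.14, Clic5 0.01, H2-Aa 1.57 and H2-Eb1 1.64 for 12 weeks minus 10 days also turned. Lars2 0.39, Fabp4 0.66, Cfd 0.58, Rpl34 1.5, Rpl9 1.79, Eif4g3 3.82, Srsf10 2.5, Ins2 2.39, H2-K1 2.21, H2-Ab1 4.32 and H2-Eb1 4.25 for 12 weeks minus 4 weeks also turned. This fit leaves any trend with brightness in place, and the cause was not tested.

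With the 2% span, called genes numbered 224 (130 higher) at 4 weeks and 173 (88 higher) for 12 weeks minus 4 weeks. The 2% span gave an odds ratio of 2.56 for chromosome 17 at 4 weeks. Called lists numbered 8 for 12 weeks minus 4 weeks. Exocrine -0.51, ribosomal -0.05 and oxidative phosphorylation -0.04 at 4 weeks, exocrine -0.3, ribosomal -0.05 and class I -0.21 for 4 weeks minus 10 days, exocrine 0.6 and ribosomal 0.17 for 12 weeks minus 4 weeks were the lists that turned with the 2% span. H2-K1 -0.03 and H2-Ab1 -0.15 at 4 weeks, H2-K1 -0.07, H2-D1 -0.79 and H2-Ab1 -0.54 for 4 weeks minus 10 days, H2-K1 0.53 and H2-Ab1 0.29 for 12 weeks minus 4 weeks were the genes that turned with the 2% span.

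With the 5% span, called genes numbered 228 (117 higher) at 4 weeks, 34 (34 higher) at 12 weeks and 178 (101 higher) for 12 weeks minus 4 weeks. The 5% span gave an odds ratio of 2.75 for chromosome 17 at 4 weeks. Called lists numbered 8 for 12 weeks minus 4 weeks. Exocrine -0.35, ribosomal 0.03 and oxidative phosphorylation -0.07 at 4 weeks, exocrine -0.3, ribosomal -0.03 and class I -0.23 for 4 weeks minus 10 days, exocrine 0.79, ribosomal 0.23 and oxidative phosphorylation 0 for 12 weeks minus 4 weeks were the lists that turned with the 5% span. H2-Ab1 -0.11 at 4 weeks, H2-K1 -0.04, H2-D1 -0.81 and H2-Ab1 -0.5 for 4 weeks minus 10 days, H2-K1 0.55 and H2-Ab1 0.25 for 12 weeks minus 4 weeks were the genes that turned with the 5% span.

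With the 1% span, called genes numbered 224 (134 higher) at 4 weeks and 177 (88 higher) for 12 weeks minus 4 weeks. The 1% span gave an odds ratio of 2.56 for chromosome 17 at 4 weeks. Exocrine -0.53, ribosomal -0.05 and oxidative phosphorylation -0.05 at 4 weeks, ribosomal 0.01 at 12 weeks, exocrine -0.29, ribosomal -0.05 and class I -0.2 for 4 weeks minus 10 days, exocrine 0.41 and ribosomal 0.03 for 12 weeks minus 4 weeks were the lists that turned with the 1% span. H2-K1 -0.04 and H2-Ab1 -0.14 at 4 weeks, H2-K1 -0.07, H2-D1 -0.77 and H2-Ab1 -0.53 for 4 weeks minus 10 days, H2-K1 0.54 and H2-Ab1 0.28 for 12 weeks minus 4 weeks were the genes that turned with the 1% span. The cause was tested, after the data were seen, only for the ribosomal and exocrine lists at 4 weeks, where equally bright genes moved by as much or more.

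With an offset of 16, called genes numbered 383 (198 higher) at 10 days, 90 (83 higher) at 12 weeks and 1415 (591 higher) for 4 weeks minus 10 days. Between ages the smaller offset gave 419 (210 higher) for 12 weeks minus 10 days. The smaller offset gave an odds ratio of 2.08 for chromosome 17 at 4 weeks. Called lists numbered 11 for 12 weeks minus 10 days and 3 for 12 weeks minus 4 weeks. Exocrine 0.45 for 12 weeks minus 4 weeks was the list that turned with the smaller offset. H2-K1 0.4 for 12 weeks minus 4 weeks was the gene that turned with the smaller offset. Without background correction, called genes numbered 59 (59 higher) at 12 weeks. The uncorrected signal gave an odds ratio of 1.73 for chromosome 17 at 4 weeks. Called lists numbered 11 for 12 weeks minus 10 days. With scale normalisation between arrays, called genes numbered 37 (18 higher) at 10 days, 33 (28 higher) at 12 weeks and 463 (329 higher) for 4 weeks minus 10 days. Between ages the scaled ratios gave 50 (32 higher) for 12 weeks minus 10 days and 239 (59 higher) for 12 weeks minus 4 weeks. Called lists numbered 4 for 12 weeks minus 10 days and 3 for 12 weeks minus 4 weeks. The cause was not tested.

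The mean of probes gave an odds ratio of 1.95 for chromosome 17 at 4 weeks. Called lists numbered 11 for 12 weeks minus 10 days. H2-K1 -0.76 and H2-Aa -0.99 at 10 days, H2-Aa -0.78 and H2-Ab1 -0.13 at 4 weeks, H2-Ab1 -0.14 for 4 weeks minus 10 days, H2-Aa 0.98 for 12 weeks minus 10 days, H2-K1 0.07 and H2-Ab1 0.14 for 12 weeks minus 4 weeks were the genes that turned with the mean of probes. For the H2 genes the averaging of probes that differ is the cause, and for the others it was not tested.

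With no limit on the fold, called genes numbered 5453 (2097 higher) at 10 days, 2810 (1037 higher) at 4 weeks and 4164 (2076 higher) for 4 weeks minus 10 days. Between ages the looser threshold gave 1809 (1150 higher) for 12 weeks minus 10 days and 948 (492 higher) for 12 weeks minus 4 weeks. The looser threshold gave an odds ratio of 1.39 for chromosome 17 at 4 weeks. With a limit of 2-fold, called genes numbered 30 (11 higher) at 10 days, 253 (248 higher) at 4 weeks and 6 (6 higher) at 12 weeks. Between ages the stricter threshold gave 262 (242 higher) for 4 weeks minus 10 days, 29 (22 higher) for 12 weeks minus 10 days and 196 (3 higher) for 12 weeks minus 4 weeks. The threshold itself is the cause.

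The share of higher calls moved by over 10 percentage points in further counts. The genes called NOD over NOD.B10 at 10 days numbered 216 (114 higher) with the 2% span and 214 (113 higher) with the 1% span. The genes called NOD over NOD.B10 at 4 weeks numbered 694 (370 higher) with an offset of 16 and 624 (434 higher) without background correction. The genes called NOD over NOD.B10 at 12 weeks numbered 18 (15 higher) with the 2% span and 17 (14 higher) with the 1% span. With the spans of 2%, 5% and 1%, genes called 4 weeks minus 10 days numbered 578 (307 higher), 567 (283 higher) and 575 (309 higher), and genes called 12 weeks minus 10 days 191 (94 higher), 217 (113 higher) and 190 (96 higher). An offset of 16 gave 537 (283 higher) genes called 12 weeks minus 4 weeks, and no background correction 454 (157 higher). Without 10-day arrays 1 and 3 the same counts were 298 (167 higher) at 10 days and 244 (109 higher) for 12 weeks minus 10 days.

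At 12 weeks the count of 12 was the least stable. It was 62 with array weights, 24 with each age alone, 24 with scan as a random block, 42 without slide 3, 20 with the stricter filter (15510 probes tested against 27802) and 51 with only genes measured in both channels. That last limit gave 16 for 12 weeks minus 10 days and 221 for 12 weeks minus 4 weeks, because fewer genes were tested. With slide as a fixed block the genes called 12 weeks minus 4 weeks numbered 108 (69 higher) and the lists 8, and with scan as a fixed block the genes numbered 434. Without the filter on dim probes 11 lists were called for 12 weeks minus 10 days. The causes were not tested.

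Leaving out 1 array at a time gave 2 genes (without 12-week array 3 or 7) to 33 (without array 1) at 12 weeks. For 12 weeks minus 10 days it gave 120 (without 10-day array 2) to 306 (without 10-day array 5). The odds ratio of chromosome 17 at 4 weeks ran from 1.49 to 1.8, the latter without 4-week array 6 (adjusted exact p = 0.016). Over all omissions 2421 named gene results were unchanged, 66 lost their call and 12 gained one, and of the list results 889 were unchanged, 39 lost and 7 gained.

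With the replicate number as a replicate block, the genes called 4 weeks minus 10 days numbered 619, the genes called 12 weeks minus 10 days 250 (193 higher) and the genes called 12 weeks minus 4 weeks 465. Arrays with the same number correlated above 0.1 in 1 of 5, 1 of 4 and 2 of 5 pairs, and 1 pair in each comparison had its own number as the highest. The numbers do not pair the arrays.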

Other observations

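The lists below were fixed before the data, while Il7r, Socs1 and Junb and the 2% span were picked after the results were seen. The lists named next, for immune cells and their products, showed no difference from NOD.B10 that passed the threshold with the 30% span, with medians given in the order 10 days, 4 weeks and 12 weeks. Class II genes (11 members) were at -0.113 (adjusted p = 0.538), -0.064 (0.9) and -0.031 (0.262). The class II gene H2-Ab1 was called higher at 10 days (0.61, adjusted p = 0.0248) and 4 weeks (1.594, adjusted p = 1.06e-05). Neither call stood with the 2% span (0.391 and -0.148) or the scanner ratio (0.469 and -0.195). Dendritic cell genes were at -0.082 (0.472), -0.029 (0.5) and -0.009 (0.981). Germinal centre and plasma cell genes were at 0.009 (0.879), -0.073 (0.63) and -0.028 (0.374), regulatory and effector T cell genes at -0.031 (0.732), -0.005 (0.465) and 0.003 (0.981), and cytotoxic and natural killer genes at -0.01 (0.879), -0.044 (0.782) and 0.009 (0.981). Interferon gamma genes were at -0.029 (0.877), -0.099 (0.63) and 0.005 (0.981), and the 2% span called them lower at 4 weeks (-0.09, adjusted p = 0.00589; adjusted p = 0.408 with an estimated correlation). Regulators tied to type 1 diabetes were at 0.002 (0.538), -0.029 (0.746) and 0.011 (0.981), though among them Il7r was lower (-0.59, adjusted p = 0.000347) and Socs1 higher (0.80, adjusted p = 0.000384) at 10 days, neither called with the scanner ratio (0.153 and 0.12). Other genes of the H2 region (71 members) were at -0.09 (0.198), -0.054 (0.765) and 0.011 (0.981).

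Lists for tissue and cell state gave the same outcome. Islet genes were at 0.03 (0.185), -0.096 (0.369) and -0.003 (0.981), skeletal muscle genes at -0.067 (0.344), -0.014 (0.846) and 0.005 (0.981), and erythroid genes at 0.003 (0.586), -0.05 (0.928) and 0.003 (0.981). Proliferation genes were at -0.067 (0.774), 0.018 (0.279) and 0.004 (0.981), circadian clock genes at -0.057 (0.344), -0.084 (0.237) and -0.004 (0.981), and immediate early and stress genes at 0.02 (0.169), 0.013 (0.212) and 0 (0.981). The 2% span called proliferation genes higher at 4 weeks (0.046, adjusted p = 0.00932; adjusted p = 0.408 with an estimated correlation), and the scanner ratio called skeletal muscle genes lower at 10 days (-0.47, adjusted p = 0.0141) and clock genes lower at 4 weeks (-0.768, adjusted p = 0.0455). The transcription factor gene Junb was at 1.16 (adjusted p = 0.000137) at 4 weeks and at 0.65 (adjusted p = 0.00129) with the 2% span, and the scanner ratio gave 0.20 (adjusted p = 0.393). These values do not exclude smaller differences, above all at 12 weeks where few genes were above background in Cy5.

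Of 6131 genes with several probes, 95 had a called probe at 10 days and 225 at 4 weeks. All probes were called in the same direction for 8 of them at 10 days and 17 at 4 weeks, and in opposite directions for 1 and 7.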
